A study of Mus musculus with 24 samples.

How the data were processed

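The series measured messenger RNA in 4 kinds of activated mouse immune cells, each from miR-155 knockout (KO) and wild-type (WT) mice on a C57BL/6J background, with 3 libraries in each of 8 groups and 24 libraries in all. Per the labels, the libraries were made with a TruSeq kit and read as paired ends on an Illumina sequencer. The series' design text calls the 3 libraries of a condition sequencing replicates and names no separate animals, so the p-values given here measure the spread between these libraries, which may be technical. Counts of library pairs within a group were compared before any averaging, over genes with at least 20 counts. Every pair differed by more than counting noise, with a chi-square per gene between 2.08 and 160.69, so no library was taken for a copy of another. Separate libraries of 1 sample would also differ by more than counting noise, so this does not show that the samples are separate.

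The deposited files hold whole-number counts of reads per gene symbol over coding sequence, with no normalization, for 20673 genes in each library. The submitters' processing notes name cutadapt, STAR and the mm9 genome build, without versions. The tool that counted the reads, the handling of strand and the settings are not given in the sources used here. Lines that name no gene were left out of library sizes and tests. The line for reads outside any counted feature held 51.4 to 61.1% of all counts in a library. Total gene counts ran from 7428821 to 14219823 per library, with 9152770 to 11473588 in B cells, 7428821 to 8281861 in dendritic cells, 11479765 to 14219823 in macrophages and 8070030 to 10495461 in CD4 T cells. The 10 most abundant genes took 15.7 to 17.9% of the gene counts in macrophages and 5.4 to 6.9% in the other cell types.

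Groups were taken from the sample titles. Within each cell type the 3 KO libraries were compared with the 3 WT libraries by edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter, and the robust quasi-likelihood F test (glmQLFit and glmQLFTest). A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Log2 fold changes are KO minus WT, and their standard errors (SE) were taken as the absolute log2 fold change divided by the square root of F. Expression is given as counts scaled to a common library total (CPM, edgeR), mean ± SD over the 3 libraries of a group. Whether the KO effect differed between cell types was tested in 1 fit of all 24 libraries with 8 group means, over the 4 cell types together and for each of the 6 pairs of cell types. That fit used the same dispersion per gene for all cell types, although the spread between libraries differed between them. All tests were two-sided. An exact permutation test of 3 against 3 libraries, used for marker sums, cannot give a p below 0.1.

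Sites for miR-155-5p were searched in the longest annotated 3' UTR of each symbol in GENCODE M21, which is on GRCm38 and not on the mm9 build of the files. Of the symbols, 19967 matched directly, 562 matched through an older name and 144 did not match, and 19944 had a 3' UTR. The site types were the 8mer AGCATTAA, the 7mer-m8 AGCATTA, the 7mer-A1 GCATTAA and the 6mer GCATTA. A gene with an 8mer or 7mer is called seed-matched, a gene with only a 6mer was placed in neither class, and coordinates given here are those of GRCm38. Seed-matched genes were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and also with an estimated correlation. The p-values of the 4 cell types were adjusted together. This adjustment was added after the unadjusted values had been seen, and among 56 such tests over all settings it changed the side of the threshold in 1, the dendritic cell test with an estimated correlation (camera p of 0.048 before and 0.087 after adjustment). All 7-mers found in at least 50 genes were also ranked by a Welch-type statistic of the fold changes, as a description without a p-value.

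The 16 gene lists for pathways and cell functions, and 12 lists of cell type markers, were fixed from general knowledge before the data were examined. The pathway lists with at least 5 tested members were tested by the same camera test, with adjustment over the lists of a cell type. Members were counted at an adjusted p under 0.05 over all genes, and also adjusted over the list alone. Named genes were chosen by a rule fixed at the same time. It took the 10 genes up and the 10 down with the largest change among called genes with a mean of 5 CPM or more and no overlap between KO and WT libraries, and the 8 called seed-matched genes with the smallest p. It also took 9 reported targets in every cell type, up to 4 members of each list, up to 15 genes called the same way in at least 3 cell types, the 10 genes with the smallest p between cell types, and the annotated neighbours of Mir155. Predicted genes and ribosomal protein pseudogenes were passed over.

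Genes of families with near-identical copies, such as Pira2, Pydc3, Ifit1bl1, Ms4a6c, Gstt1 and Gstt3, and the class II genes of the H2 locus, can share reads, and their values are uncertain. The same holds for Tmem176a and Tmem176b, whose annotated spans overlap.

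The count and camera steps were tested on simulated counts with known changes, and the ranking step on random fold changes raised for genes with a chosen 7-mer. Changes of single genes were planted only in genes with a mean above 5 CPM, so the shares recovered do not describe genes below that level. Of genes changed 2-fold, 100% were recovered in B cells, 97% in dendritic cells, 69.7% in macrophages and 100% in CD4 T cells, over 10092, 10446, 10651 and 10338 tested genes. Of genes changed 1.5-fold, 83.6, 65.7, 7.5 and 88.1% were recovered in the same order. False calls made up 8.6 to 9.6% of simulated calls, above the nominal 5%. The test over 4 cell types recovered 68.5% of genes changed 2-fold, over 12183 genes, with 0.7% false calls. Its simulation changed genes in dendritic cell KO alone and drew all cell types with the same dispersion per gene. The real cell types differ in spread, so 0.7% does not describe the error of the real calls between cell types.

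Replicate numbers are shared by the KO and WT groups of a cell type, so it was checked whether libraries with the same number deviated together from their group means. In macrophages the correlations of same-numbered libraries were 0.125 to 0.386 and all 6 libraries correlated best with their own number. By this check from the data, the numbers may pair the macrophage samples, although no label says so. KO replicate 1 correlated nearly as well with WT replicate 2 (0.112) as with WT replicate 1 (0.125). With 3 libraries in each group few pairings are possible, so such a match can also arise by chance. A fit with the replicate number as a block is given beside the macrophage results it changes. In the other cell types at least 1 correlation was below 0.1, and the numbers were not treated as pairs. In B cells 5 of the 6 libraries still correlated best with their own number, with same-numbered correlations of 0.028 to 0.213. In dendritic cells and in CD4 T cells 2 libraries did so. The labels number the B cell WT libraries in more than one way, so the B cell numbers, which follow the titles, are uncertain.

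Alternatives were DESeq2's size factors in the edgeR fit, DESeq2 1.42.0, no expression filter, a filter of 1 CPM in at least 3 libraries, the replicate block, all 24 libraries in 1 fit, each library left out in turn, the shortest 3' UTR, genes without a site matched on 3' UTR length, 8mer sites alone, an estimated correlation and fry. Summaries and exact tests were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9.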

Results

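Messenger RNA was sequenced from activated B cells, dendritic cells, macrophages and CD4 T cells of miR-155 knockout (KO) and wild-type (WT) mice. miR-155 is a microRNA of activated immune cells that binds sites in the 3' UTR of messenger RNAs and lowers their level. The title of the series asks how the cellular context changes gene regulation by this microRNA. B cells from spleen were activated with IL-4 at 6.5 ng/ml together with LPS at 25 ug/ml. Dendritic cells were CD11c-positive spleen cells from mice that carried B16 melanoma cells making Flt3 ligand, and received 100 ng/ml LPS and 20 ng/ml GM-CSF. Macrophages were elicited in the peritoneum with thioglycollate and received 100 ng/ml LPS. CD4 T cells without CD25 and CD44 were activated with beads carrying antibodies to CD3 and CD28. Each of the 8 groups held 3 libraries, with 7428821 to 14219823 gene counts per library, 9152770 to 11473588 in B cells, 7428821 to 8281861 in dendritic cells, 11479765 to 14219823 in macrophages and 8070030 to 10495461 in CD4 T cells.

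Mir155 and its host gene Mir155hg are not among the gene symbols of the count files, so the KO label could not be checked on the targeted gene itself. In the GRCm38 annotation, Mir155 lies on chromosome 16 from 84714140 to 84714204, within the noncoding gene Mir155hg. The neighbouring gene Mrpl39, which encodes a protein of the mitochondrial ribosome, lies on the other strand from 84717576 to 84735742, with 2331 bases between the 2 genes. Mrpl39 fell in KO in all 4 cell types, from 84.2 ± 1.18 to 64.2 ± 5.78 CPM in B cells, from 39.1 ± 1.52 to 18.8 ± 2.70 in dendritic cells, from 40.8 ± 1.18 to 21.5 ± 3.80 in macrophages and from 81.6 ± 2.48 to 54.5 ± 3.31 in CD4 T cells (SD, n = 3). Its log2 fold changes were -0.39, -1.05, -0.92 and -0.58, with edgeR adjusted p of 0.0048, 0.00021, 0.046 and 0.00052. Farther along the chromosome, Jam2 in macrophages was not called (-3.21, SE 0.69, adjusted p = 0.084) but was past the threshold with the replicate block (adjusted p = 0.014). Atp5j, beyond Jam2, was not called in any of the 4 cell types.

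Genes with a miR-155 site stood higher in KO than genes without a site in every cell type. The median log2 fold change of seed-matched genes exceeded that of genes without a site by 0.061 in B cells, 0.171 in dendritic cells, 0.128 in macrophages and 0.043 in CD4 T cells. Without B cell KO replicate 1 the B cell value was 0.027 (adjusted p = 0.022). Among seed-matched genes, 101 rose and 9 fell in B cells, 352 rose and 82 fell in dendritic cells, 17 rose and 1 fell in macrophages, and 55 rose and 8 fell in CD4 T cells. Adjusted over the list alone, these counts were 141 and 15, 388 and 95, 34 and 4, and 95 and 16. The share that rose was 7.2, 24.1, 1.1 and 3.8%, against 1.3, 9.9, 0.4 and 0.9% of genes without a site. The limma camera test gave adjusted p of 2.5e-05 in B cells, 7.1e-07 in dendritic cells, 2.5e-05 in macrophages and 0.0012 in CD4 T cells. With an estimated correlation the call held only in CD4 T cells (adjusted p = 0.018) and was lost in B cells (adjusted p = 0.13), dendritic cells (adjusted p = 0.087) and macrophages (adjusted p = 0.087). With genes without a site matched on 3' UTR length, the differences were 0.072, 0.134, 0.069 and 0.052 in the same order, with adjusted p of 2.8e-05, 9e-05, 0.0096 and 0.00038, so that in macrophages the value fell by more than 1.5 times.

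In each cell type the difference was highest for genes with an 8mer and lowest for those with a 6mer alone, and differences between site types were not tested. Genes with an 8mer exceeded genes without a site by 0.102, 0.246, 0.219 and 0.080 on the log2 scale in B cells, dendritic cells, macrophages and CD4 T cells. The corresponding values were 0.041, 0.159, 0.108 and 0.028 for genes with a 7mer-m8 site, 0.056, 0.136, 0.099 and 0.034 for a 7mer-A1 site and 0.005, 0.087, 0.082 and 0.014 for a 6mer alone. Among all 7-mers of the 3' UTRs, AGCATTA ranked 1 of 16040 in dendritic cells, and 2 in both B cells and CD4 T cells behind GCATTAA, which is also a miR-155 site. In macrophages it ranked 22 of 16059, and the leading 7-mer was TTTTTAA.

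**Figure D1:**
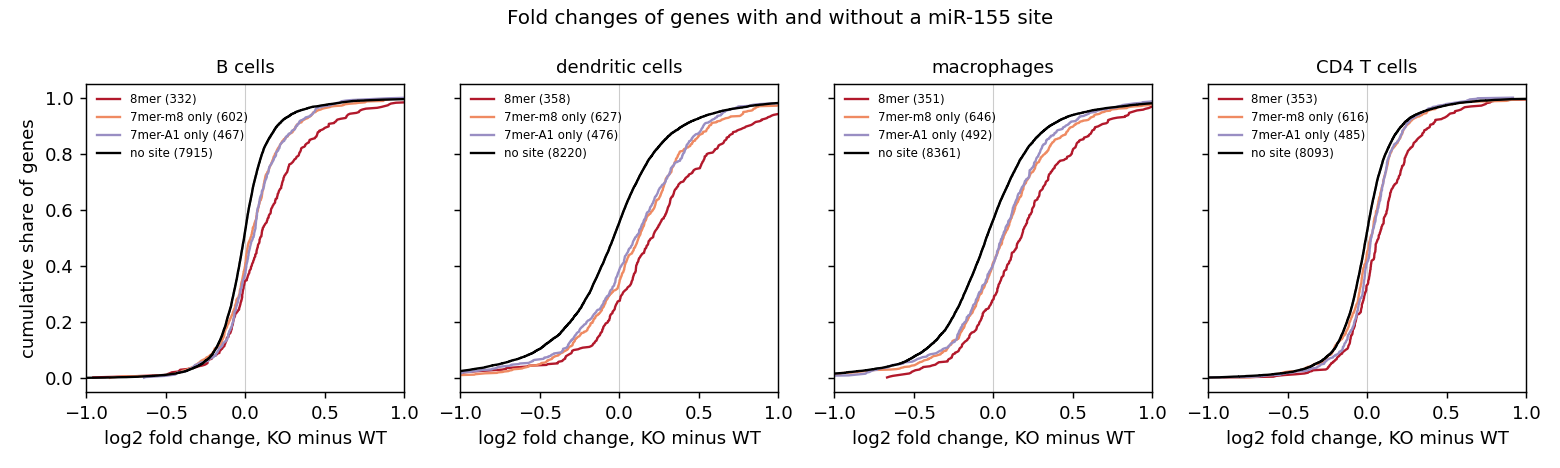
Cumulative share of genes (y axis) by log2 fold change, KO minus WT (x axis, shown from -1 to 1), in each cell type, for genes with an 8mer, with a 7mer-m8 or 7mer-A1 site as the best site, and without a site, with the number of genes in brackets. The 8mer curve lies to the right of the curve for genes without a site in all 4 panels, with median differences of 0.102, 0.246, 0.219 and 0.080.

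In activated B cells the repressor Bach1 rose from 10.9 ± 0.393 to 22.8 ± 1.55 CPM (SD, n = 3), a log2 fold change of 1.07 (SE 0.1). The histone methyltransferase cofactor Jarid2 rose by 0.90 and the clathrin adaptor Picalm by 0.89, and all 3 carry a site. Of 10151 genes tested, 325 were called, 212 up and 113 down, with a median size of 0.44 on the log2 scale. Among called genes with a mean of 5 CPM or more and no overlap between KO and WT libraries, strong increases were those in Wdfy1 (1.66), the prostacyclin receptor Ptgir (1.24), the chemokine Ccl22 (1.22), Fmnl2 (1.20), Lad1 (1.13), Myo10 (1.09), Tmem176b (1.08) and Tmem176a (1.05). The strongest decreases among these genes were in Pydc3 (-3.67), Mid1 (-2.69), Cdh17 (-0.93), the bicarbonate transporter Slc4a8 (-0.85), Ssbp2 (-0.84), the cytokine lymphotoxin alpha Lta (-0.76), Akap12 (-0.74), Hemgn (-0.73), Nlrc3 (-0.70) and Tespa1 (-0.67). Further seed-matched genes that rose were Gsr (1.04), Nfe2l2 (0.92), Rheb (0.82), Sgk3 (0.72), Uap1 (0.72) and Csnk1g2 (0.64).

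The list of reported miR-155 targets rose in B cells, with 16 of 32 tested members up, none down and 16 not called. Its camera adjusted p was 9.8e-19, and adjusted p = 0.051 with an estimated correlation. Adjusted over the list alone, 21 rose and 1 fell. Members that rose included Tab2 (0.52), Spi1 (0.57), a transcription factor of B and myeloid cells, Cebpb (0.95), Peli1 (0.42) and Inpp5d (0.21), the phosphatase SHIP1. Socs1, an inhibitor of cytokine signalling with an 8mer site, was not called at -0.07 (SE 0.12). The oxidative stress and iron list rose (adjusted p = 4.4e-10, and adjusted p = 0.061 with an estimated correlation), with 5 of 16 members up, 0 down and 11 not called, and 10 up adjusted over the list alone. They were Gsr, Nfe2l2, Txnrd1 (0.48), Fth1 (0.40) and Ftl1, where Nfe2l2 encodes the regulator NRF2 and the others encode enzymes of thiol reduction and the subunits of ferritin. The lysosome and lipid efflux list rose with 5 of 21 members up, among them Cd36 (0.80), Lamp1 (0.20) and Lamp2 (0.24), 0 down and 16 not called, and 7 up and 1 down adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.39 with an estimated correlation). The cholesterol synthesis list was shifted down with 0 of 23 members called, also adjusted over the list alone (adjusted p = 0.033, and adjusted p = 0.77 with an estimated correlation). The p53 response and apoptosis list was shifted up with 0 of 21 called and 3 up adjusted over the list alone (adjusted p = 0.033, and adjusted p = 0.39 with an estimated correlation).

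The other 11 lists were not called in B cells, with adjusted p from 0.057 to 0.94. In the list for B cell activation and plasma cell differentiation (adjusted p = 0.94), Tnfrsf13c (-0.35) and Spib (-0.24) fell, and its mean was above 0 while its median and test were below. In the cell cycle list (adjusted p = 0.19), the replication genes Mcm2 (0.37) and Cdt1 (0.42) rose and 36 members were not called. Of the type I interferon list (adjusted p = 0.49) Ddx58 fell (-0.31) and no other member was called, and of the glycolysis and hypoxia list (adjusted p = 0.22) Vegfa rose (0.56) and Hk1 fell (-0.36). Il2rb of the T helper list (adjusted p = 0.073) fell (-1.59), and Il6ra of the naive T cell and homing list (adjusted p = 0.58), Egr1 of the immediate early and heat shock list (adjusted p = 0.057) and Cd40 of the antigen presentation list (adjusted p = 0.45) rose, by 0.87, 0.57 and 0.22. The mean of the interferon and cytokine signalling feedback lists was above 0 and their median below it. Summed B cell markers were 4232 ± 168 CPM in KO and 4392 ± 182 in WT, and plasma cell markers 395 ± 61.7 and 333 ± 40.2 (SD, n = 3), with exact permutation p of 0.4 and 0.3, where Mzb1 made up 341 and 302 CPM of the plasma cell sum. Without WT replicate 1, WT replicate 2 or KO replicate 2, the count of called genes was 141, 150 or 156. It was 81 in the fit of all 24 libraries, 501 without the expression filter and 1260 with the replicate number as a block, where the labels number the B cell WT libraries in more than one way and the titles were followed. Among the called lists, cholesterol synthesis was lost without KO replicate 2 (adjusted p = 0.19), WT replicate 1 (0.2) or WT replicate 3 (0.95). So was p53 response without KO replicate 3 (0.13) or WT replicate 2 (0.17), and lysosome and lipid efflux without WT replicate 2 (0.058). Lists called with a library left out but not with all were type I interferon without KO replicate 3 (adjusted p = 8.1e-05) or WT replicate 1 (0.03), and inflammatory without KO replicate 2 (0.011), WT replicate 1 (0.028) or WT replicate 3 (0.0038). So were T helper without KO replicate 3 (0.034), immediate early without KO replicate 1 (0.0061) or WT replicate 3 (0.021), and integrated stress response without KO replicate 2 (0.0054) or WT replicate 3 (0.001). With the replicate block the inflammatory (0.017) and immediate early (0.027) lists were called. Both calls were lost with an estimated correlation added to the block (adjusted p of 0.38 and 0.4).

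In dendritic cells the lists of interferon response genes and reported targets stood higher in KO and those of lysosome and cholesterol synthesis genes lower, 4 calls that were each lost with an estimated correlation (adjusted p = 0.46). Markers of macrophages were also lower in KO, at 111 against 272 CPM. Of 10536 genes tested, 2279 were called, 1286 up and 993 down, with a median size of 0.53. Arginase 2 (Arg2) rose from 11.1 ± 1.43 to 52.1 ± 3.80 CPM and Ass1, an enzyme of arginine synthesis, from 94.0 ± 10.2 to 314 ± 11, log2 fold changes of 2.23 (SE 0.12) and 1.74 (SE 0.09), and both carry a site. Slc4a8 rose from 427 ± 17.5 to 1125 ± 24.1 CPM and Uap1 from 959 ± 54.1 to 2261 ± 140 (SD, n = 3). Among called genes with a mean of 5 CPM or more and no overlap between the groups, the largest increases besides Arg2 were in Ifit1bl1 (2.93), Clu (2.32), Gstt1 (2.28), Gfpt2 (2.19), Chst7 (2.13), Peli2 (2.11), the extracellular superoxide dismutase Sod3 (1.99), Upb1 (1.90) and Asprv1 (1.90). The largest decreases among these genes were in Pira2 (-5.77), Rab44 (-2.81), Fam149a (-2.04), Ms4a6c (-1.90), Txlnb (-1.88), the histidine decarboxylase Hdc (-1.80), Zdhhc9 (-1.78), Ip6k3 (-1.77), Lamtor4 (-1.77) and Ppil3 (-1.72). Further seed-matched genes that rose were Pmaip1 (1.54), a member of the BCL2 family that promotes apoptosis, Rps6ka5 (1.49), Nfe2l2 (1.49) and the nuclear receptor Nr4a3, which stood at 650 ± 23.6 against 272 ± 22.7 CPM (SD, n = 3).

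Reported targets rose in dendritic cells, with 17 of 36 up, 1 down and 18 not called, and 19 up and 1 down adjusted over the list alone (adjusted p = 3.8e-05, and adjusted p = 0.46 with an estimated correlation). Bach1 (1.03), Picalm (0.85), Peli1 (0.71), Spi1 (0.69) and Tab2 (0.54) rose, Inpp5d fell (-0.29), and Jarid2 (-0.09), Socs1 (0.10), Maf (0.04) and Cebpb (-1.06, SE 0.49) were not called. The type I interferon list rose with 15 of 35 up, 2 down and 18 not called, and 19 up and 2 down adjusted over the list alone (adjusted p = 0.00024, and adjusted p = 0.46 with an estimated correlation). Ifit2 (1.74), Mx1 (0.95) and Herc6 (0.50) rose and Oasl2 (-0.67) fell. The lysosome and lipid efflux list fell with 8 of 24 members down, 1 up and 15 not called, and 9 down and 1 up adjusted over the list alone (adjusted p = 0.0029, and adjusted p = 0.46 with an estimated correlation). In the same libraries macrophage markers summed to 111 ± 14 CPM in KO and 272 ± 143 in WT (SD, n = 3), with 434 in WT replicate 3. By camera the list was also called without that library (adjusted p = 0.009). The WT libraries that remained, at 164 and 217 CPM, still stood above the KO libraries, at 97.9 to 126. That setting therefore does not separate the list from the macrophage markers. The scavenger receptor Cd36 (-1.09) and the lysosomal regulator Tfeb (-0.83) fell while Lamp1 (0.46) rose. The cholesterol synthesis list fell with 8 of 23 members down, 0 up and 15 not called, and 10 down and 1 up adjusted over the list alone (adjusted p = 0.0061, and adjusted p = 0.46 with an estimated correlation), among them Dhcr7 (-0.89), Lss (-0.53), Mvd (-0.50) and Sqle (-0.46).

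The other 12 lists were not called in dendritic cells, with adjusted p from 0.051 to 0.52, and several held members that moved both ways. Among inflammatory genes, Cxcl3 (1.28), Il1b (0.77) and Birc3 (0.54) were among 7 that rose and Ccl22 (-0.77) among 4 that fell. Among antigen presentation genes, the costimulatory ligands Icosl (1.0), Pdcd1lg2 (0.80) and Cd274 (0.78) were among 4 that rose and H2-DMb1 (-0.79) among 2 that fell. In the naive T cell and homing list 7 members rose, among them Il7r (0.84) and Tcf7 (0.88), and Itgb7 alone fell (-1.47). In the p53 response and apoptosis list 6 rose, among them Plk2 (0.60), and 2 fell, among them Bcl2l1 (-0.90). Of the integrated stress response and amino acid list (adjusted p = 0.12), Phgdh (-1.42) and Slc7a5 (-0.36) were among 5 members that fell and Wars alone rose (0.57). The cytokine signalling feedback list (adjusted p = 0.27) had 7 members up and 4 down, with a mean below 0 and a median and test above it. Markers of macrophages summed to 164, 217 and 434 CPM in the WT libraries. Markers of neutrophils summed to 1.90 ± 0.326 in KO and 7.29 ± 6.19 in WT, markers of B cells to 29.1 ± 4.04 and 17.6 ± 5.46, stromal and mesothelial markers to 1.47 ± 0.114 and 3.23 ± 0.344, and markers of conventional dendritic cells to 14622 ± 282 and 12088 ± 413 (SD, n = 3). For each of these 5 sums the exact permutation p was 0.1. The neutrophil sum was mostly Csf3r (1.43 and 6.15 CPM), and in the WT libraries it stood at 3.74, 3.7 and 14.4, highest in replicate 3. Fscn1 alone, at 7981 and 5447 CPM, made up the difference in the dendritic cell sum, while Ccr7 stood at 4524 and 4540. The cholesterol synthesis list was not called without WT replicate 1 (adjusted p = 0.05). Lists called with a library left out but not with all were glycolysis and hypoxia without KO replicate 2 (adjusted p = 0.002), KO replicate 3 (0.0071) or WT replicate 3 (0.026). So were naive T cell and homing without KO replicate 2 (0.048), KO replicate 3 (0.036) or WT replicate 2 (0.017), and immediate early without KO replicate 2 (0.049). The glycolysis and hypoxia list was also called with a filter of 1 CPM in at least 3 libraries (adjusted p = 0.047) and with the replicate block (0.016). With an estimated correlation its adjusted p was 0.61, and 0.64 with the block added. Without KO replicate 1, 2 or 3 or WT replicate 3 the count of called genes was 1464, 1176, 1279 or 1483. Without WT replicate 3, the library with the most macrophage transcripts, and KO replicate 3 it was 666, a setting chosen after seeing the data.

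In macrophages 4 of 22 genes on the integrated stress response and amino acid list rose in KO, a list whose call was lost with an estimated correlation (adjusted p = 0.28). In the same libraries stromal and mesothelial markers summed to 469 ± 207 CPM in KO, with 703 in KO replicate 3, and 232 ± 104 in WT (SD, n = 3; exact permutation p = 0.2). Of these genes, asparagine synthetase (Asns) rose from 6.73 ± 1.89 to 41.0 ± 16 CPM and the cystine transporter Slc7a11 from 193 ± 41.1 to 524 ± 28.8. Outside the list, Arg2 rose from 93.0 ± 30.7 to 284 ± 7.79 (SD, n = 3). Their log2 fold changes were 2.61 (SE 0.34), 1.44 (SE 0.17) and 1.61 (SE 0.23). Of 10730 genes tested, 95 were called, 59 up and 36 down, with a median size of 1.27, and with the replicate block 265 were called, 171 up and 94 down. Other large increases were in the calcium channel gene Cacna1b (2.19), the amino acid transporter Slc7a5 (2.02), the oncostatin M receptor Osmr (1.96), the clock repressor Nr1d1 (1.95), Ttc28 (1.88), Boc (1.86), the serine synthesis enzyme Phgdh (1.70) and Sox4 (1.70). Among called genes with a mean of 5 CPM or more and no overlap between the groups, the largest decreases were in S100a4 (-2.80), Tmem176b (-2.78), Pld4 (-2.03), Stap1 (-2.03), the adhesion molecule Pecam1 (-1.64), Plbd1 (-1.62), the proton-sensing receptor Gpr65 (-1.45), Syt11 (-1.39), the transporter Abcc3 (-1.38) and the actin regulator Coro1a (-1.34). The seed-matched genes Picalm (0.89), Gnl3l (0.87), Hn1l (0.86), Wbp1l (0.85), Zfp652 (0.85) and D15Ertd621e (0.70) also rose.

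The integrated stress response and amino acid list rose in macrophages with 4 of 22 members up, 0 down and 18 not called, and 14 up adjusted over the list alone (adjusted p = 1.1e-10, and adjusted p = 0.28 with an estimated correlation). The 4 were Slc7a11, Asns, Phgdh and Slc7a5, which make or import amino acids, in libraries whose stromal and mesothelial sum was higher in KO. Reported targets rose with 2 of 37 up (Picalm and Zfp652), 0 down and 35 not called, and 10 up adjusted over the list alone (adjusted p = 1.4e-06, and adjusted p = 0.28 with an estimated correlation). Jarid2 (0.99, SE 0.20) and Bach1 (0.78, SE 0.15) were not called, with adjusted p of 0.081 and 0.066, and were past the threshold with the replicate block, with adjusted p of 0.033 and 0.043. Socs1 was measured at 55.3 ± 4.32 CPM in KO and 59.3 ± 46.0 in WT (SD, n = 3). The lists for glycolysis and hypoxia (adjusted p = 0.00066, and adjusted p = 0.43 with an estimated correlation), cholesterol synthesis (adjusted p = 0.00099, and adjusted p = 0.89 with an estimated correlation) and type I interferon response (adjusted p = 0.0047, and adjusted p = 0.89 with an estimated correlation) were shifted down with 0 members called. Adjusted over the list alone, 5 glycolysis and hypoxia genes fell and 0 of the other 2 lists were called. Between WT replicates 3 and 2 the interferon list itself differed by a median log2 value of 0.74, with 29 of 32 genes higher in replicate 3, and the cholesterol list by -0.47, with 19 of 23 lower. The interferon list was not called without KO replicate 1 (adjusted p = 0.066), KO replicate 2 (0.075), WT replicate 1 (0.37) or WT replicate 3 (0.1). The oxidative stress and iron list had 2 members up, Slc7a11 and Txnrd1 (0.88), and was called with the replicate block (adjusted p = 0.028, and adjusted p = 0.76 with an estimated correlation) but not without it (adjusted p = 0.06, and adjusted p = 0.89 with an estimated correlation). It was also called with a filter of 1 CPM in at least 3 libraries (adjusted p = 0.03), and without KO replicate 1 (adjusted p = 0.048), KO replicate 3 (0.041), WT replicate 1 (0.048) or WT replicate 2 (0.00016).

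The other 10 lists were not called in macrophages, with adjusted p from 0.21 to 0.85. The inflammatory list (adjusted p = 0.64) was called down without WT replicate 2 (adjusted p = 0.032) and up without WT replicate 3 (0.0038). Without WT replicate 3 the cytokine signalling feedback (0.018) and lysosome (0.00036) lists were also called, and without KO replicate 3 the cell cycle list (0.015). Ccl17 fell (-3.12), the costimulatory ligand Tnfsf9 rose (1.05), and Apoe (-1.05, SE 0.43) and Fabp4 (-1.54, SE 0.74), genes of lipid handling, were not called. The median, mean and test differed in sign for the inflammatory, T helper, naive T cell and immediate early lists. The WT libraries differed widely among themselves, with Apoe at 2718 to 10004 CPM in WT libraries and 2653 to 3226 CPM in KO libraries. Conventional dendritic cell markers summed to 324 ± 35.8 CPM in KO and 214 ± 30.6 in WT, and macrophage markers to 31066 ± 1275 and 31931 ± 5008 (SD, n = 3), with exact permutation p of 0.1 and 0.8. The dendritic cell sum was mostly Itgax, at 312 and 200 CPM, with Flt3, Zbtb46, Xcr1 and Ccr7 near 0. The macrophage sum was mostly Lyz2 (17438 and 16033 CPM). In that list C1qa (546 and 1437), C1qb (342 and 1136), C1qc (235 and 904) and Fcgr1 (140 and 302) were lower in each KO library than in any WT library. Csf1r alone (3283 and 2910) was higher in each. Leaving out single libraries ended nearly all calls in edgeR, with 0 called without KO replicate 1, KO replicate 2 or WT replicate 1 (1125, 1213 and 1208 genes at an unadjusted p under 0.05) and 1 without KO replicate 3, while 148 were called without WT replicate 2 and 2746 without WT replicate 3. DESeq2 called 586 genes on all 6 libraries and the fit of all 24 libraries 1755.

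In CD4 T cells the aspartic protease gene Ctse was nearly lost in KO, from 54.8 ± 2.10 to 1.16 ± 0.655 CPM (SD, n = 3), a log2 fold change of -5.62 (SE 0.18). The cytokine Il2 fell from 17.9 ± 2.64 to 9.53 ± 1.69 CPM and Tnf from 32.3 ± 2.92 to 19.9 ± 3.16, while reported targets rose. Of 10396 genes tested, 223 were called, 140 up and 83 down, with a median size of 0.42. Among called genes with a mean of 5 CPM or more and no overlap between the groups, the largest increases were in the glutathione transferases Gstt1 (2.03) and Gstt3 (1.52), Epcam (1.46), Tmem176b (1.31), Bzrap1 (1.15), the xanthine dehydrogenase Xdh (1.03), Rasgrp2 (1.0), Marveld2 (0.93), Matk (0.91) and Ccl22 (0.89). Besides Ctse and Il2 (-0.90), the largest decreases among these genes were in the complement regulator Cd55 (-1.58), Cd160 (-0.90), Kdelc1 (-0.87), the receptor kinase Axl (-0.85), Galm (-0.84), Entpd4 (-0.84), Traf3ip1 (-0.81) and Gucy1b3 (-0.80). Seed-matched genes that rose included Jarid2 (0.80), Abhd16a (0.64), Sdcbp (0.61), Nfe2l2 (0.60), Tspan14 (0.59), Trp53inp1 (0.52), Tab2 (0.49) and Csnk1g2 (0.48).

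Reported targets rose in CD4 T cells with 10 of 35 up, 0 down and 25 not called, and 15 up adjusted over the list alone. Their camera adjusted p was 1.9e-14, and adjusted p = 0.012 with an estimated correlation. With the replicate block added to the estimated correlation, a setting chosen after seeing the data, the call was lost (adjusted p = 0.38). Besides Jarid2 and Tab2, Bach1 (0.60), Picalm (0.52), Ets1 (0.32) and Inpp5d (0.29) rose, while Socs1 (0.04), Peli1 (0.05), Cebpb (0.29) and Spi1 (1.07, SE 0.43) were not called. The antigen presentation list rose with 3 of 24 up, 0 down and 21 not called, and 10 up and 1 down adjusted over the list alone (adjusted p = 6.3e-07, and adjusted p = 0.52 with an estimated correlation). The 3 were H2-Ab1 (0.56), H2-Oa (1.04) and Ciita (1.16), the class II genes and their activator. Summed B cell markers, which stand beside this list, were 57.5 ± 17 CPM in KO and 36.3 ± 11.2 in WT (SD, n = 3; exact permutation p = 0.2). Subtracting the B cell profile took H2-Aa, H2-Eb1 and H2-DMb2 to 0 in all 6 libraries and Ciita in 4. It moved H2-Ab1 from 0.56 to 0.29 and the median of all 24 members from 0.359 to 0.145. The median of the 20 other members went from 0.22 to 0.173, a choice of members made after seeing the data. The adjusted p of these 20 after the subtraction was 0.0081, and adjusted p = 0.52 with an estimated correlation. The oxidative stress and iron list rose with Nfe2l2 and Gsr (0.27) up, 0 down and 13 not called, and 3 up adjusted over the list alone (adjusted p = 0.0075, and adjusted p = 0.52 with an estimated correlation). The type I interferon list was shifted up with 0 of 32 members called and 1 up adjusted over the list alone (adjusted p = 3.7e-07, and adjusted p = 0.69 with an estimated correlation). The naive T cell and homing list was shifted up with 0 of 17 called and 2 up adjusted over the list alone (adjusted p = 0.03, and adjusted p = 0.69 with an estimated correlation).

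The other 11 lists were not called in CD4 T cells, with adjusted p from 0.13 to 0.90. In them, Mcm2 (0.22) rose and Plk2 (-0.59), Ier2 (-0.34) and Hexa (-0.32) fell, and in the cytokine signalling feedback list (adjusted p = 0.51) Inpp5d was the 1 member called. The median, mean and test differed in sign for the inflammatory, cholesterol, T helper and immediate early lists. T cell markers summed to 2796 ± 18.8 CPM in KO and 2963 ± 58.8 in WT (SD, n = 3; exact permutation p = 0.1). Without KO replicate 1, 2 or 3 the count of called genes was 32, 68 or 47, and without WT replicate 1, 2 or 3 it was 598, 34 or 409. It was 63 in the fit of all 24 libraries and 478 without the expression filter. The naive T cell and homing list was not called without KO replicate 1 (adjusted p = 0.056), KO replicate 3 (0.14) or WT replicate 3 (0.065). Lists called with a library left out but not with all were glycolysis and hypoxia (adjusted p = 0.0016) and lysosome and lipid efflux (0.046) without WT replicate 3, and integrated stress response without WT replicate 1 (0.0074) or 2 (0.04).

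The KO effect differed between cell types for 1548 of 12249 genes, tested over the 4 cell types together in edgeR. Slc4a8, which carries a 7mer-m8 site, rose in dendritic cells (1.40), fell in B cells (-0.85) and was near 0 in CD4 T cells (-0.03), with an adjusted p of 3.6e-06. Ass1 rose by 1.74 in dendritic cells and 0.47 in B cells, and was 0.54 in macrophages and 0.16 in CD4 T cells. In macrophages Slamf1 (2.74) and Slc7a5 (2.02) rose and Stap1 (-2.03) and Fgd2 (-3.16) fell. In dendritic cells Slamf1 rose by 0.62 and Slc7a5 fell by 0.36 on the log2 scale, and no other call was made for these genes in B cells, dendritic cells or CD4 T cells. Arl5c rose in dendritic cells (1.16) and CD4 T cells (0.80) and fell in macrophages (-0.69), Cd82 fell in dendritic cells (-0.89) and rose in macrophages (0.61), and Lpcat1 rose in dendritic cells (0.78) and fell in B cells (-0.27). Ctse fell in CD4 T cells and was 0.32 (SE 0.35) in B cells, with only 9 to 20 counts in each B cell library. Of 40 reported targets the difference was called for 10, among them Jarid2 (adjusted p = 0.00099), Inpp5d (0.0013), Peli1 (0.007), Ets1 (0.017), Ptpn2 (0.031), Cebpb (0.037) and Rheb (0.047).

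**Figure D2:**
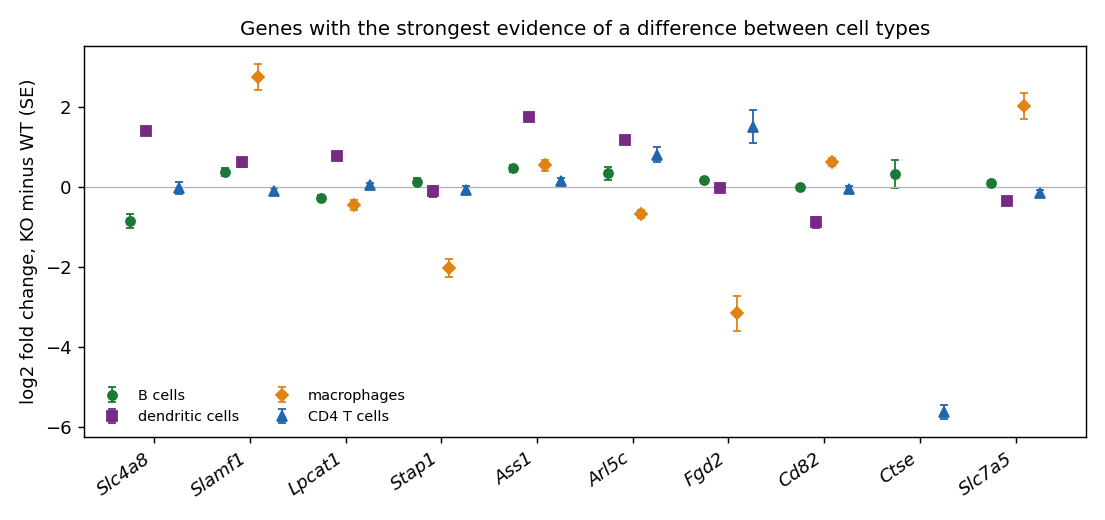
Log2 fold change, KO minus WT (y axis), with SE as bars, of the 10 genes with the smallest p for a difference between cell types (x axis), from the separate fit of each cell type, with no point where a gene did not pass the expression filter. Slc4a8 stands at 1.40 in dendritic cells and -0.85 in B cells, and Ctse at -5.62 in CD4 T cells.

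Pairs of cell types differed in very different numbers of genes, in 1 fit with a dispersion per gene shared by all cell types. The coefficient of variation between libraries beyond counting noise was 0.177 in macrophages, 0.096 in dendritic cells, 0.058 in B cells and 0.061 in CD4 T cells. That fit called more genes in macrophages and fewer in B and CD4 T cells than the separate fits did. The counts by pair and over the 4 cell types may partly reflect the shared dispersion, which was not tested. The KO effect differed for 690 genes between B cells and dendritic cells, 327 between B cells and macrophages, 7 between B cells and CD4 T cells, 1136 between dendritic cells and macrophages, 747 between dendritic cells and CD4 T cells and 445 between macrophages and CD4 T cells. Seed-matched genes differed between B cells and dendritic cells by -0.105 (adjusted p = 0.013, and adjusted p = 0.27 with an estimated correlation) and between dendritic cells and CD4 T cells by 0.127 (adjusted p = 0.0029, and adjusted p = 0.25 with an estimated correlation). The other 4 pairs were not called, with adjusted p from 0.073 to 0.26. With genes matched on 3' UTR length the differences were -0.057 (adjusted p = 0.19) and 0.087 (adjusted p = 0.17). The KO effect on the integrated stress response and amino acid list was higher in macrophages than in CD4 T cells (adjusted p = 2.9e-13, and adjusted p = 0.044 with an estimated correlation). This KO effect was also higher in macrophages than in B cells (adjusted p = 3.9e-10, and adjusted p = 0.11 with an estimated correlation) and dendritic cells (adjusted p = 8.1e-11, and adjusted p = 0.092 with an estimated correlation). Stromal and mesothelial markers in macrophages summed to 469 CPM in KO and 232 in WT. The KO effect on the antigen presentation list was higher in CD4 T cells than in B cells (adjusted p = 1.9e-08, and adjusted p = 0.072 with an estimated correlation). B cell markers summed to 57.5 CPM in KO and 36.3 in WT CD4 T cells. Subtracting the B cell profile took 4 members to 0 in at least 1 library. It took the CD4 T cell median of the whole list from 0.359 to 0.145 and that of the other 20 members from 0.22 to 0.173. The KO effect on the type I interferon list was lower in macrophages than in dendritic cells (adjusted p = 4.6e-05, and adjusted p = 0.73 with an estimated correlation). Between macrophage WT replicates 3 and 2 this list differed by a median log2 value of 0.74, with 29 of 32 genes higher in replicate 3. Macrophage markers summed to 111 CPM in KO and 272 in WT dendritic cells. Without macrophage WT replicate 3 the counts were 2148 for B cells and macrophages, 2337 for dendritic cells and macrophages and 2054 for macrophages and CD4 T cells, and 3619 over the 4 cell types. DESeq2 called 565, 45 and 718 genes for B cells and macrophages, B and CD4 T cells, and macrophages and CD4 T cells.

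Several single libraries moved these pairwise counts by more than 1.5 times. For B cells and dendritic cells the count was 443, 456 or 432 without B cell WT replicate 1 or 2 or dendritic cell KO replicate 2, and for dendritic and CD4 T cells it was 497, 486 or 457 without dendritic cell KO replicate 2, CD4 T cell KO replicate 1 or WT replicate 2. For B cells and macrophages it was 204 or 159 without B cell KO replicate 2 or 3, 149 or 166 without B cell WT replicate 1 or 2, 152 or 199 without macrophage KO replicate 1 or 2, and 180 without macrophage WT replicate 1. For macrophages and CD4 T cells it was 286 or 295 without macrophage KO replicate 1 or 2, 274 without CD4 T cell KO replicate 1 or 3, and 234 without CD4 T cell WT replicate 2. For B and CD4 T cells it was 2 to 4 without B cell KO replicate 1 or 3, any B cell WT library, CD4 T cell KO replicate 1 or WT replicate 2. The call for seed-matched genes between B cells and dendritic cells was lost without B cell KO replicate 3 (adjusted p = 0.058) or dendritic cell WT replicate 1 (adjusted p = 0.083), and that between dendritic and CD4 T cells without dendritic cell WT replicate 1 (adjusted p = 0.05). Between macrophages and CD4 T cells it was gained without macrophage KO replicate 2 (adjusted p = 0.035) or WT replicate 3 (adjusted p = 0.015).

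Genes called in the same direction in at least 2 cell types numbered 199, of which 145 were up, and 82 of these carried a site (56.6%). In at least 3 cell types 39 genes were called the same way, 34 up and 5 down, and 29 of the 34 carried a site (85.3%). In all 4 cell types Picalm, Zfp652, Wbp1l, Hn1l and Kbtbd2 rose, each with a site, and Mrpl39 fell. In B cells, dendritic cells and CD4 T cells Nfe2l2, Csnk1g2, Abhd16a, Tab2, Setd8, Dennd6a, Tspan14, Selt, Ppp1cb, Bach1 and Tmem176a rose, and Pkp3 fell by 0.55, 0.70 and 0.76 on the log2 scale. Rasal3 fell in B cells, dendritic cells and macrophages. In macrophages Tmem176a and Tmem176b stood lower in KO, at -2.26 (SE 0.49, not called, but called with the replicate block at an adjusted p of 0.026) and -2.78. Between pairs of cell types, 88 genes rose in both B cells and dendritic cells against 22.45 for independent lists, 40 in B and CD4 T cells against 2.75, 64 in dendritic and CD4 T cells against 15.28 and 20 in dendritic cells and macrophages against 4.82. The cell types share no libraries. Across genes, which are not independent replicates, Spearman correlations of fold changes were 0.043 to 0.262 over all genes and 0.32 to 0.487 over genes with an 8mer. Left-out libraries, settings chosen after seeing the data for these shared counts, changed the count for all 4 cell types to 0 in edgeR without macrophage KO replicate 1, 2 or 3 or WT replicate 1, where macrophages had 0 or 1 called genes (1125, 1213 and 1208 at an unadjusted p under 0.05 without KO replicate 1, KO replicate 2 and WT replicate 1). It was 2, 3 or 3 without CD4 T cell KO replicate 1, KO replicate 3 or WT replicate 2, 21 without macrophage WT replicate 3, and 11 with the macrophage block. The count for at least 3 cell types was 22, 23 or 20 without CD4 T cell KO replicate 1, KO replicate 2 or WT replicate 2 and 76 without macrophage WT replicate 3, and that for at least 2 was 672 without this last library.

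**Figure D3:**
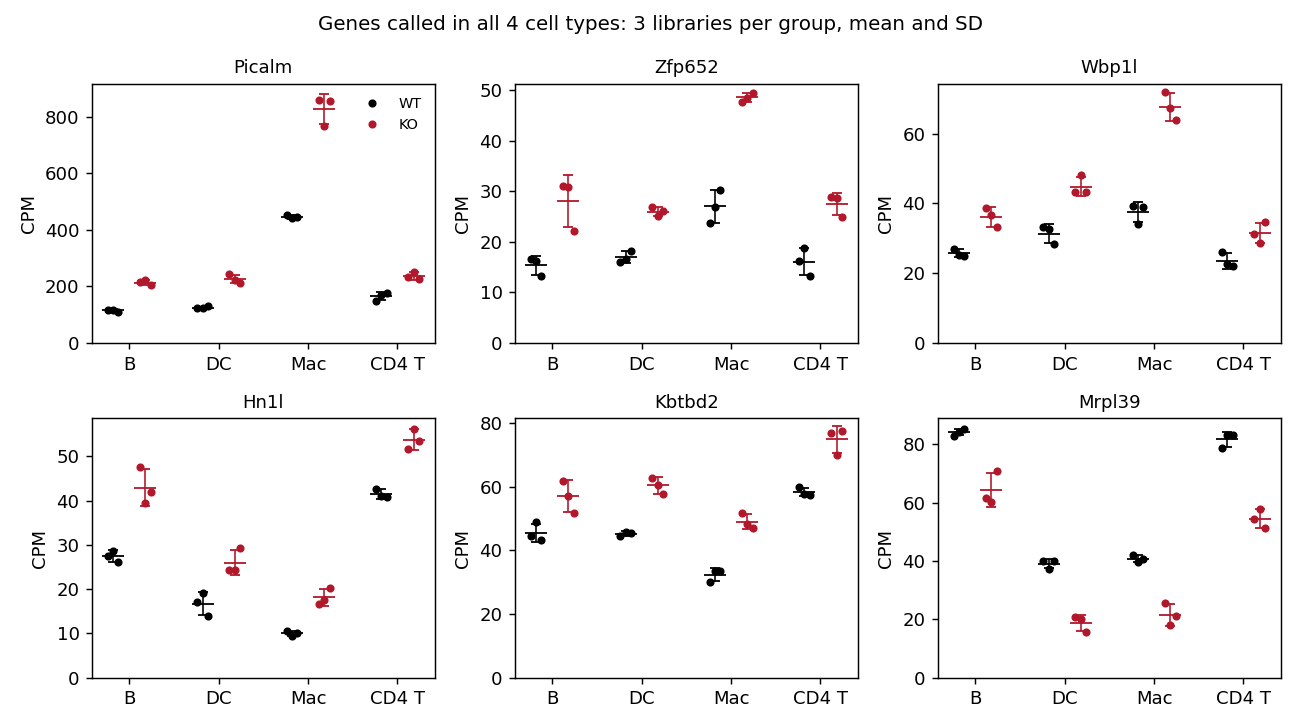
CPM (y axis, from 0) of the 6 genes called in the same direction in all 4 cell types (x axis), with 3 WT libraries in black and 3 KO libraries in red as points and the mean and SD as bars. Mrpl39 lies lower in KO in each cell type, at 64.2 against 84.2 CPM in B cells, and the other 5 genes lie higher.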

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

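The tests of Mrpl39, of Ctse and of the macrophage WT libraries were chosen only after the results had been seen. So were the splits that part the macrophage pairs or keep dendritic cell KO and WT apart. The B cell subtraction, an estimated correlation after it and the antigen presentation genes that it does not take to 0 were also chosen then. The tests of all other splits of the libraries were written before.

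The KO effect differed between the 4 cell types for 1548 genes, by the test of the difference itself. That fit used a dispersion per gene shared by cell types whose spread between libraries differed. By pair it differed for 690 genes between B cells and dendritic cells, 327 between B cells and macrophages, 7 between B and CD4 T cells, 1136 between dendritic cells and macrophages, 747 between dendritic and CD4 T cells and 445 between macrophages and CD4 T cells. Among 100 splits of the libraries within cell types, the real one included, the number with as many genes was 1 over the 4 cell types (highest other 1270), 1 for B cells and dendritic cells (583), 1 for B cells and macrophages (295), 2 for B and CD4 T cells (35), 3 for dendritic cells and macrophages (2628), 1 for dendritic and CD4 T cells (656) and 1 for macrophages and CD4 T cells (176), so chance can be excluded only for a grouping unrelated to genotype. Splits that mix KO and WT remove the KO effects themselves and do not test whether equal effects in the cell types would give these counts. The splits that keep KO and WT apart in dendritic cells number 10, too few for a share under 0.05, with highest others of 1270 over the 4 cell types, 583 for B cells and dendritic cells, 2628 for dendritic cells and macrophages and 656 for dendritic and CD4 T cells.

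The replicate numbers may pair the macrophage libraries. Among the 43 of these splits that part all 3 same-numbered macrophage pairs the number with as many genes was 1 over the 4 cell types (highest other 547), 1 for B cells and macrophages (295), 2 for dendritic cells and macrophages (1531) and 1 for macrophages and CD4 T cells (176). The split with 35 genes points to a structure of the samples that is the genotype itself, since it keeps KO and WT apart in B cells and CD4 T cells and exchanges the labels in one of them, and that with 2628 keeps KO and WT apart in dendritic cells and sets macrophage KO replicate 2 and WT replicates 1 and 2 against the other 3.

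Seed-matched genes differed by -0.105 between B cells and dendritic cells and by 0.127 between dendritic and CD4 T cells. Of the 100 splits, 29 and 17 gave as large a difference, with highest others of 0.276 and 0.184. The 100 include splits that keep KO and WT apart, the real one among them. They number 12 in B cells, 10 in dendritic cells, 11 in macrophages and 7 in CD4 T cells. Such splits keep a KO effect, and splits that mix KO and WT weaken it. The splits therefore do not decide whether the differences arose by chance, and chance cannot be excluded. For the pairs of B cells and macrophages (real 0.063 in size), B and CD4 T cells (0.017), dendritic cells and macrophages (0.041) and macrophages and CD4 T cells (0.072) the numbers were 48, 70, 71 and 38, with highest others of 0.209, 0.095, 0.326 and 0.159, and chance cannot be excluded there either.

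Within 1 cell type the 6 libraries make 10 splits, too few for a share under 0.05. The number with a result as large was 1 for the called genes of each cell type (real 325, 2279, 95 and 223 in B cells, dendritic cells, macrophages and CD4 T cells, highest other 0, 1, 0 and 3). It was 2, 1, 2 and 1 for the seed-matched difference (real 0.061, 0.171, 0.128 and 0.043, highest other 0.082, 0.118, 0.13 and 0.025) and 7, 6, 7 and 6 for the number of gene lists called (real 5, 4, 5 and 5, highest other 10, 6, 10 and 9). In macrophages, whose numbers may pair the libraries, the 3 other splits that part all 3 same-numbered pairs called 0 genes each in edgeR. Their seed-matched differences were 0.104, 0.031 and 0.002, and the split with 0.13 keeps a same-numbered pair together.

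The genes with the smallest p for a difference between cell types were Slc4a8, Slamf1, Lpcat1, Stap1, Ass1 and Arl5c (adjusted p = 3.6e-06 each), Fgd2 (4e-06), Cd82 (4.1e-06), Ctse (4.2e-06) and Slc7a5 (4.4e-06). The effect differed for 10 of 40 reported targets, among them Jarid2 (adjusted p = 0.00099), Inpp5d (0.0013), Peli1 (0.007), Ets1 (0.017), Ptpn2 (0.031), Cebpb (0.037) and Rheb (0.047), and among all named genes for 131. The number of gene lists called between cell types was 4 for each pair but macrophages and CD4 T cells, where it was 7, and with an estimated correlation it was 0 for each pair but that one, where it was 1.

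Mrpl39, next to Mir155, fell in KO in all 4 cell types and Ctse fell in CD4 T cells, and neither carries a site. Loss of repression would raise a target, and the highest log2 fold change of Mrpl39 over the 4 cell types was -0.39, which argues against direct targeting. A strain segment around Mir155 and an effect of the deletion itself cannot be told apart. Of 44 other genes without a site within 10 Mb, 0 were called the same way in at least 3 cell types. Only 39 genes in all were called so, and 0 of 44 therefore decides little. A strain variant that acts on Mrpl39 alone would also leave no trace in other genes. Bach1, left out of the 44 because it carries a site, lies in this window, from 87698945 to 87733346, and rose in B cells, dendritic cells and CD4 T cells. For Ctse, 5 of 47 genes without a site within 10 Mb were called in CD4 T cells (Cd55, Cxcr4, Eif2d, Lad1 and Rnpep, 10.6% against a median of 1.4%), the percentile being 100 among 7442 overlapping windows of other chromosomes, so a linked strain segment is a candidate explanation. In B cells Ctse did not fall (log2 fold change 0.32, SE 0.35). Its counts there were 12, 13 and 20 in the KO libraries and 9, 15 and 9 in the WT libraries. These values argue against a fall in B cells as large as that in CD4 T cells. Counts this low could still hide a smaller fall. Dendritic cells had at most 4 counts in a library and macrophages at most 1. The counts in dendritic cells and macrophages are too few to tell a KO effect on Ctse shared by these 2 cell types from one in CD4 T cells alone.

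The macrophage WT libraries differed from each other, with Il6 at 93.6 CPM in WT replicate 3 and 4.2 in WT replicate 2, a gene chosen after its values were seen. A difference in the strength of the LPS response may account for this. The inflammatory list had a median log2 difference of 1.28 between these libraries, with 29 of 30 genes higher in replicate 3. The lysosome and lipid efflux list had one of -0.73, with 24 of 26 lower. Il6 is itself a member of the inflammatory list, and the lists were compared after the difference had been seen, so they are not independent support. Neutrophils in replicate 3 are argued against by S100a9, an abundant neutrophil transcript, at 0 CPM there, as were Ly6g and Ngp. The sum of neutrophil markers was still 664 CPM there against 509 and 498 in the other WT libraries, of which Csf3r made up 613, 455 and 463. In that list S100a8 stood at 46.19 CPM in replicate 3 against 49.93 and 32.77, and Camp at 4.41 against 3.46 and 1.41. Stromal cells cannot be told apart from a difference in response, since their markers summed to 340 CPM in replicate 3 against 224 and 133 in the other WT libraries, 1.52 times the higher one, and moved with the difference. Library size is argued against by a ratio of 1.14 between replicates 2 and 3, and the cause of a different response was not tested.

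Antigen presentation genes stood higher in CD4 T cell KO libraries, where B cell markers made up 0.863 to 1.56% of the B cell level, against 0.666 to 1.12% in WT. Subtracting the B cell profile took H2-Aa, H2-Eb1 and H2-DMb2 to 0 in all 6 libraries and Ciita in 4. There the subtracted share was at least as large as the reads seen, so B cell transcripts could account for them. The subtracted profile was that of the WT B cells activated with LPS and IL-4. B cells carried into the CD4 T cell libraries may hold other levels of these genes, so the subtraction may take too much or too little, which was not tested. Over all 24 members the median log2 fold change went from 0.359 to 0.145 (camera adjusted p = 0.0096 after it, and adjusted p = 0.4 with an estimated correlation). Genes at 0 in all libraries enter that median with a fold change of 0. For the other 20 the median log2 fold change went from 0.22 to 0.173 (median absolute deviation 0.302 and 0.271). For these 20, B cell transcripts cannot be told apart from a KO effect in the T cells themselves, since this change is smaller than the spread of the members. After the subtraction the 20 genes were called with the preset correlation (adjusted p = 0.0081) and not with an estimated one (adjusted p = 0.52, and 0.66 before the subtraction), so a KO effect in the T cells stays open.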

How the results depend on the processing

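The tests chosen only after results were seen were the macrophage block or any left-out library in the count of shared genes, the block with an estimated correlation, and leaving out 2 libraries at once in macrophages or dendritic cells. Where results moved, the cause was not tested, except that leaving out a library leaves fewer samples. Called genes in B cells numbered 501 without a filter, 1260 with the replicate block and 81 with all 24 libraries in 1 fit. In macrophages they numbered 586 in DESeq2, 265 with the block, 1755 with 24 libraries and 1479 without WT replicates 2 and 3, in CD4 T cells 478 without a filter and 63 with 24 libraries, and in dendritic cells 666 without WT replicate 3 and KO replicate 3. Between cell types DESeq2 gave 565 genes for B cells and macrophages, 45 for B and CD4 T cells and 718 for macrophages and CD4 T cells. The seed-matched difference with an estimated correlation was 0.061 in B cells (adjusted p = 0.13), 0.171 in dendritic cells (0.087) and 0.128 in macrophages (0.087), and with the block added 0.06 (0.16), 0.169 (0.15) and 0.133 (0.15). It was -0.105 (0.27) between B cells and dendritic cells and 0.127 (0.25) between dendritic and CD4 T cells with an estimated correlation, -0.057 (0.19) and 0.087 (0.17) with matched 3' UTR length, and 0.093 (0.024) between macrophages and CD4 T cells for 8mers alone. The site ranked 2 among 7-mers of the shortest 3' UTRs in dendritic cells. In B cells, dendritic cells, macrophages and CD4 T cells, 0, 0, 0 and 1 lists were called with an estimated correlation, 0 in each with the block added, and 2, 11, 2 and 2 by fry. Genes shared by at least 2 cell types numbered 420 with 24 libraries and 672 without macrophage WT replicate 3, by at least 3 76 without that library, and by 4 12 with 24 libraries, 14 in DESeq2, 21 without that library and 11 with the macrophage block. With 1 library left out at a time they ran from 146 to 672 for at least 2, from 20 to 76 for at least 3 and from 0 to 21 for 4 cell types, with 0 without macrophage KO replicate 1, 2 or 3 or WT replicate 1. Leaving out 1 library at a time gave 141 to 441 called genes in B cells, 1176 to 2870 in dendritic cells, 0 to 2746 in macrophages (1125 at an unadjusted p under 0.05 for the 0 without KO replicate 1) and 32 to 598 in CD4 T cells. It gave 1121 to 3619 over the 4 cell types, 432 to 821 for B cells and dendritic cells, 149 to 2148 for B cells and macrophages, 2 to 10 for B and CD4 T cells, 848 to 2337 for dendritic cells and macrophages, 457 to 799 for dendritic and CD4 T cells and 234 to 2054 for macrophages and CD4 T cells. Seed-matched differences ran from 0.027 to 0.085 in B cells, 0.135 to 0.218 in dendritic cells, 0.1 to 0.191 in macrophages and 0.036 to 0.045 in CD4 T cells. By pair, in the order above, they ran from -0.133 to -0.072, -0.107 to -0.015, 0 to 0.043, -0.008 to 0.069, 0.093 to 0.161 and 0.054 to 0.121. Called lists ran from 3 to 7, 3 to 7, 4 to 7 and 4 to 6. The macrophage inflammatory list turned in direction without WT replicate 2 (adjusted p = 0.032), in a range of 0.0038 to 0.8 over left-out libraries. For single named genes, 2367 values kept their direction and side of the threshold under other settings, 166 passed it and 85 fell short, and 2168, 100 and 354 did so with a library left out. The 10 genes with the smallest p between cell types kept their call under each of 5 other settings and without each of the 24 libraries. Macrophages limit detection most, since 7.5% of simulated 1.5-fold changes were recovered there.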

Other observations

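No test in this part was chosen only after a result was seen, and the values come from marker lists fixed before the data were examined.

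Siglech, a marker of plasmacytoid dendritic cells, stood at 20.3 ± 7.55 CPM in KO and 21 ± 7.18 in WT dendritic cells (SD, n = 3) and at 0 in B cells, where Ly6d (144 and 145), Bst2 (109 and 106), Spib (104 and 123) and Tcf4 (95.3 and 89.3) of the same list stood higher. Markers of CD8 T and NK cells summed to 22.3 ± 5.32 CPM in KO and 27.9 ± 15.8 in WT CD4 T cells, mostly Nkg7 (9.82 and 18.2) and Cd8b1 (6.52 and 5.24), and to 43.6 ± 8 and 42.6 ± 7.84 in dendritic cells, mostly Gzma (12 and 13.1) and Klrd1 (11 and 13.1). B16 melanoma cells were injected to obtain dendritic cells, and their markers Mlana, Tyr, Tyrp1, Dct, Sox10, Gpr143 and Slc45a2 were at 0 in all dendritic cell libraries, while Pmel (0.953 in KO and 1.82 in WT) and Mitf (1.11 and 1.93) were above 0. Erythroid markers summed to 10.8 ± 12.2 and 4 ± 3.61 CPM in KO and WT B cells, mostly Alas2 (8.11 and 2.4), with 24.9 in KO replicate 3 and 5.14 and 2.52 in the other KO libraries. Cpa3, Mcpt8, Fcer1a, Ms4a2 and Epx, markers of mast cells, basophils and eosinophils, were at 0 in all B cell libraries, while Il5ra (17 in KO and 20 in WT) and Prg2 (0.877 and 0.343) were above 0.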
